A study of Mus musculus with 9 samples.

How the data were processed

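RNA was measured in MLE-12 mouse lung epithelial cells in 9 samples: 3 with regular medium, 3 with extracellular vesicles from lavage fluid of bleomycin-injured wild-type mice, and 3 with vesicles of injured syndecan-1 deficient mice. Per the labels, cells at passage 17 were grown in DMEM with fetal bovine serum, RNA was isolated with Trizol and libraries were made with the TruSeq stranded mRNA kit. The submitters' processing notes name TopHat2 (version 2.0.7) and the genome builds GRCm38 and mm10, and state neither the read counter nor the annotation release. The authors deposited 1 table of RPKM for 21950 genes with 1 column per sample, per the file headers. The labels do not state vesicle dose, duration of treatment or the meaning of the tag D21 in the column names. Nor do they say whether the 3 samples of a group had separate donors or vesicle preparations. Columns for vesicle-treated samples carry the donor type and a number. Control columns carry only the name of the line and a number, and were assigned to the controls by elimination. All 9 value columns were used, and 0 were left unused.

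Gene identifiers were matched to GENCODE release M21 on GRCm38 for coordinates. Of the 21950 genes 21748 matched and 202 did not, and 41 symbols were shared by more than 1 gene and kept apart by identifier. RPKM was 0 in all samples for 3743 genes. Coordinates are 1-based start and end of the annotated gene. For each annotated gene the share of its exonic 50-base sequences that occur in another annotated gene was computed, since reads from such sequences cannot be assigned with certainty.

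RPKM values of low genes lay on whole multiples of a step set by gene and library, which allowed the library totals and whole reads to be recovered. The totals were between 24353257 and 33558660 reads. Reads were recovered for 17424 of the 18207 genes above 0 (95.7%), for 48.9% of them with the annotated gene length, and 99.02% of values above 0 were whole within 0.01. All 11125 tested genes were recovered. The recovery was tested on simulated data: 3806 of 4000 simulated genes were recovered, 100% of these with exact reads.

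The tests used log2(RPKM + 1) of genes with a mean RPKM of at least 1 over all 9 samples, which left 11125 genes. A linear model with 3 groups was fitted with limma (version 3.58.1, R 4.3.3), and 3 contrasts were tested with moderated statistics and a trend of the variance on expression. The p values of each contrast were adjusted by Benjamini-Hochberg, and genes with an adjusted p under 0.05 are called. Differences among the 3 groups were tested with the moderated F statistic of the same fit. RPKM were not rescaled further in the reported values. Error values after ± are the SD over 3 samples for RPKM and the moderated standard error for log2 fold changes. Because of the added 1, log2 fold changes of low genes are smaller than the ratio of their mean RPKM. Groups that did not overlap are those in which all 3 values of 1 group lie beyond all 3 of the other.

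Gene lists, 34 in number, were written before the data were examined, and the 27 with at least 5 tested members were tested. They cover the TGF-beta pathway, extracellular matrix and fibrosis, epithelial-mesenchymal transition, Wnt, p53 and senescence, apoptosis, interferon response, NF-kB and inflammation, alveolar type 2, type 1 and transitional epithelium, S phase, G2 and M phase, cholesterol synthesis, lipid synthesis and uptake, unfolded protein and integrated stress responses, NRF2 and oxidative stress, hypoxia and glycolysis, immediate early genes, heat shock, heparan sulfate and syndecans, vesicles and endosomes, the microRNA machinery, ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded genes and histones. The 7 lists not tested hold nuclear long noncoding RNAs and markers of macrophages, neutrophils, lymphocytes, fibroblasts, airway cells, and endothelial and erythroid cells, and their summed RPKM or single members are reported. Camera in limma, which compares a list with all other genes, was used with a preset correlation between genes of 0.01, and again with the correlation estimated per list. Fry in limma tests whether a list's genes move on balance in 1 direction, or in either, and does not compare them with other genes. List p values were adjusted over the 27 lists. The 3 lists of MYC targets, FOXO targets and gastric genes, written after the list results were known, were adjusted over these 3, and again over all 30 lists. Counts of members called are over the adjustment for all genes unless stated otherwise.

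Genes named in the text follow a rule set with the lists. Per comparison they are the 12 largest positive and 12 largest negative log2 fold changes among called genes whose groups do not overlap, without predicted gene models, up to 4 members per list with the smallest p, and Sdc1. Members named as exceptions within a list, and the 7 genes with opposite calls, were chosen after the values were seen.

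The 2 comparisons with control share the 3 control samples. The correlation of their log2 fold changes was therefore set beside 100 simulations of groups without effects that share controls. Principal components were computed on centred log2(RPKM + 1) of the tested genes in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

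The tests were tried on simulated data with the spread of the real libraries, averaged per gene over the 3 groups. Of 50 genes each with true folds of 1.25, 1.5, 2 and 4, 54%, 90%, 98% and 100% were called, with 6, 0 and 8 false calls in the 3 comparisons, and the list test called the 1 shifted list and 0 of the others. In this simulation, changes well below 1.5-fold were therefore often missed. Few simulated genes were changed, and genes varied independently without an offset between replicates. Its rates and false calls do not carry over to the comparisons with control, where 75.07% and 75.24% of genes were called and the adjustment is less strict. All simulated groups had the same spread, unlike the real ones. The 8 false calls therefore do not carry over to the comparison between preparations either.

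The alternatives tried were a pseudocount of 0.1, no filter on low values, a mean RPKM of at least 5, rescaling by median-of-ratios factors, robust moderation, library weights, a fit with only the 2 groups compared, the replicate number as a block, and leaving out each sample in turn. Chosen after seeing the data were limma-voom on the recovered reads, leaving out wild-type vesicle replicates 1 and 2 together, and only genes that share no 50-base sequence with another gene. Where a group is left with 1 sample, that sample is assumed to vary like the other groups. Calls were also counted for other splits of the samples, 10 for each pair of groups and 100 drawn for all 9. Splicing, allele-specific and sequence-level questions were left out, since sequence reads were not used here.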

Results

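MLE-12 is an epithelial cell line derived from lung tumours of mice that express a viral large T antigen under the promoter of surfactant protein C, a gene of alveolar type 2 cells. Cells at passage 17 received regular medium or extracellular vesicles, membrane-bound particles that carry protein and RNA between cells. The vesicles came from lung lavage fluid of mice injured with bleomycin, a drug used to produce lung fibrosis, and the donors were either wild type or deficient for syndecan-1, a cell-surface heparan sulfate proteoglycan of epithelia. The 3 groups are called control, wild-type vesicles and syndecan-1 deficient vesicles here, with 3 libraries of polyadenylated RNA in each. Expression was deposited as RPKM, reads scaled by gene length and by the library total, for 21950 genes. Library totals recovered from the RPKM values were 29915060, 33558660 and 25024077 reads in control, 24353257, 25561761 and 26338900 with wild-type vesicles, and 28605783, 29854695 and 32785456 with syndecan-1 deficient vesicles. The comparisons ask how lung epithelial cells respond to vesicles of injured lungs, and whether that response differs when the donor lacks syndecan-1.

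Treatment with vesicles separated the libraries more than any other feature of the design. The first principal component of the tested genes held 84.8% of the variance and placed the 3 controls between -39.6 and -38.9, and all 6 vesicle-treated libraries between 17.4 and 20.9. The second component held 10.2% and lay among the vesicle-treated cells. On it, wild-type replicates 1 and 2 stood at 14.4 and 17.2 and wild-type replicate 3 at -2.41, nearer to the syndecan-1 deficient libraries at -6.82, -13.3 and -9.71. A moderated F test over the 3 groups called 9335 of 11125 tested genes, 83.9%.

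**Figure D1:**
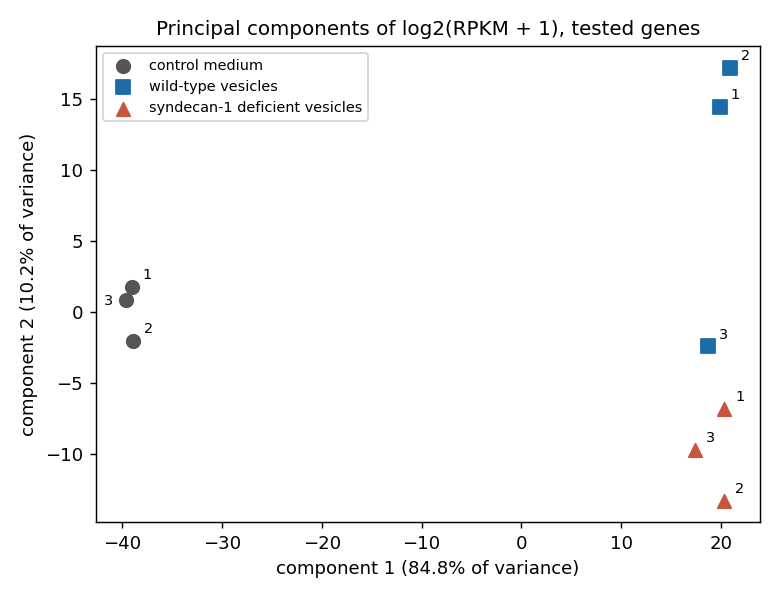
First and second principal components of log2(RPKM + 1) over the tested genes, 1 point per library, marked by group and numbered by replicate. Controls lie on the left, and wild-type vesicle replicate 3 lies at -2.41 on the second component, apart from replicates 1 and 2 of its group at 14.4 and 17.2.

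Sdc1, the gene missing in the deficient donors, lies on chromosome 12 at 8771323 to 8793715 (GRCm38, plus strand, ENSMUSG00000020592). The recipient cells were not edited, so its level describes the response of MLE-12 cells and does not check the labels. Sdc1 stood at 69.2, 66.9 and 66.0 RPKM in control, at 52.1, 52.2 and 59.9 with wild-type vesicles, and at 50.6, 58.1 and 55.7 with syndecan-1 deficient vesicles. It fell with both preparations, by 0.30 ± 0.066 on the log2 scale (standard error) with wild-type vesicles and by 0.29 ± 0.066 with deficient ones, at limma adjusted p of 0.00197 and 0.00208. Between the preparations the log2 difference was 0.0026 at an adjusted p of 0.98. With wild-type replicates 1 and 2 left out, a choice made after seeing the data, the wild-type difference was -0.17 with an adjusted p of 0.071, in a range of 6.21e-06 to 0.071 over the alternatives.

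The first comparison asks what vesicles of injured wild-type lungs do to epithelial cells. No group received vesicles of uninjured mice, so no part of the response can be tied to the injury. Interferon-response genes rose, the G2 and M phase genes, ribosomal protein genes and antioxidant genes fell, and markers of alveolar type 2 cells rose. None of these 5 list calls held with the correlation between genes estimated (adjusted p = 0.146 to 0.416 with an estimated correlation), and the type 2 call was also lost on leaving out any of 4 single libraries, where its median stayed between 0.43 and 0.46. Of 42 tested interferon-response genes, 41 rose and 1, Cxcl10, fell, and their median log2 fold change of 1.45 was the highest of the 27 lists tested. The list was called by camera at an adjusted p of 3.79e-09, against adjusted p = 0.416 with an estimated correlation. Ifit2, which encodes an interferon-induced RNA-binding protein, rose from 12.5 ± 0.87 to 36.9 ± 1.5 RPKM (SD, n = 3 in each group), and the guanylate-binding protein gene Gbp7 from 0.688 ± 0.060 to 3.65 ± 0.29. The Ifit2 relatives Ifit3 and Ifit3b were among the 12 largest increases at log2 fold changes of 3.85 ± 0.10 and 3.13 ± 0.090, but share 50.2% and 43.0% of their 50-base sequences with other genes, so the split of reads between them is uncertain. The interferon-inducible gene Ifi27l2a rose as well, by a log2 fold change of 2.84 ± 0.18. Cxcl10, an interferon-induced chemokine, was 3.30 ± 0.068 RPKM in control and 1.95 ± 0.092 with wild-type vesicles, and is named after the values were seen, like the other members given below as exceptions to the direction of a list.

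The largest increase of all named genes was that of Ptgds, prostaglandin D2 synthase, on chromosome 2 at 25466709 to 25470046. It rose from 0.439 ± 0.13 to 36.8 ± 4.1 RPKM, a log2 fold change of 4.71 ± 0.084 at an adjusted p of 3.91e-10. Wif1, a secreted Wnt inhibitor on chromosome 10 at 121033960 to 121100650, rose from 0.164 ± 0.043 to 13.4 ± 1.6 RPKM. Mgp, which encodes an inhibitor of calcification, reached 34.9 ± 8.9 from 3.70 ± 0.87, and Agt, which encodes angiotensinogen, 21.2 ± 2.3 from 2.48 ± 0.30. The other leading increases were Cbr2, Mlana, Myct1, Appl2 and Rapsn, with log2 fold changes between 2.54 and 3.11. Among the decreases, Ccnd1, which encodes cyclin D1 and lies on chromosome 7 at 144929931 to 144939925, fell from 142 ± 2.1 to 31.9 ± 0.71 RPKM, and the cyclin D2 gene Ccnd2 from 19.4 ± 0.19 to 3.72 ± 0.056. Mt2, a metallothionein gene on chromosome 8, fell from 140.1 ± 13 to 19.0 ± 2.8. The trefoil factor genes Tff1 and Tff2 stood at 4.37 ± 0.88 and 4.0 ± 0.15 RPKM in control, while Tff2 was listed at 0 in all 3 wild-type vesicle libraries and Tff1 at 0, 0.0818 and 0. Bcas1, Ly6a, Vsig1, Sorbs2 and the mast cell protease genes Mcpt1 and Cma1 were also among the 12 largest decreases, with log2 fold changes between -2.82 and -2.06.

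**Figure D2:**
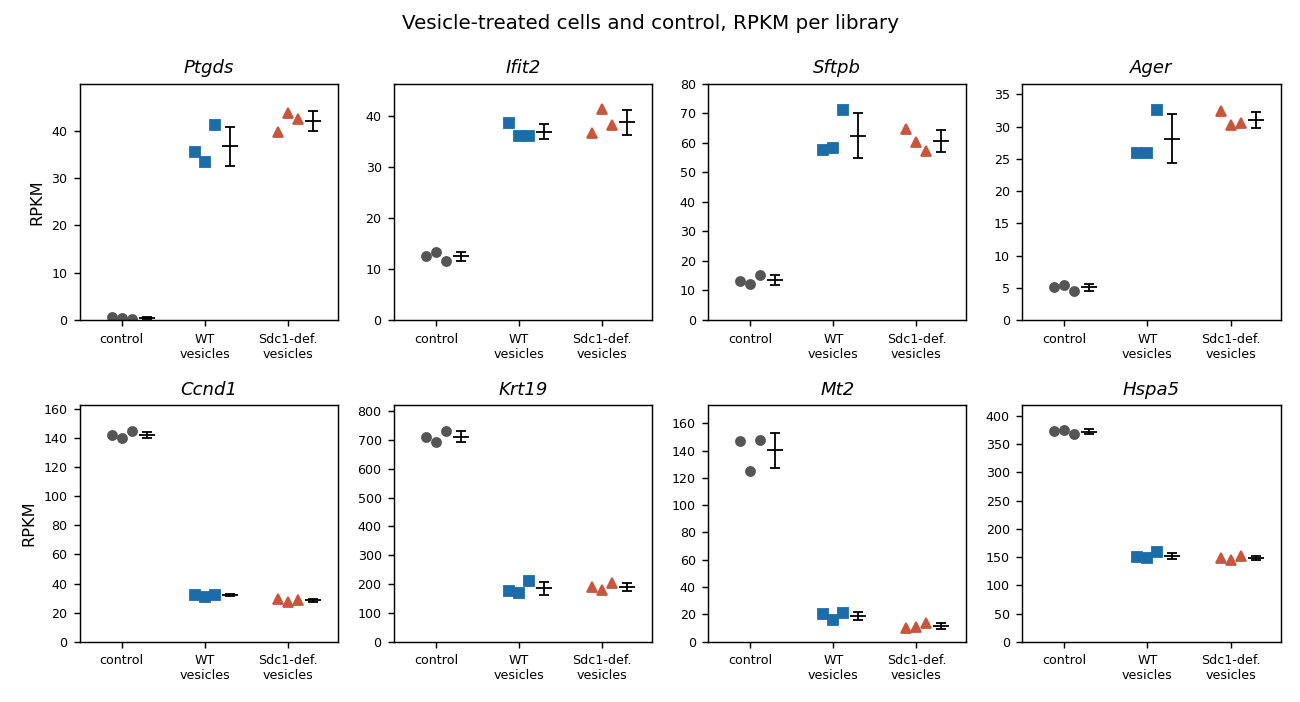
RPKM of 8 named genes per library on linear axes from 0, with markers for libraries and black bars for the group mean ± SD (n = 3). Vesicle-treated libraries of both preparations lie above control for Ptgds, Ifit2, Sftpb and Ager and below it for Ccnd1, Krt19, Mt2 and Hspa5.

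Genes of cell division and protein synthesis fell with wild-type vesicles. Of 35 tested G2 and M phase genes 34 fell and 0 rose (camera adjusted p = 6.83e-12, adjusted p = 0.178 with an estimated correlation). The checkpoint kinase gene Bub1 went from 32.6 ± 0.31 to 13.4 ± 1.2 RPKM and cyclin A2, Ccna2, from 83.0 ± 0.54 to 46.8 ± 1.7. S phase genes were not called by camera against the other genes: 16 of 34 rose and 4 fell (adjusted p = 0.515, fry FDR 9.74e-05 upward), or 12 and 11 after rescaling by median-of-ratios factors, with Pcna rising from 219 ± 1.3 to 401 ± 10.4 RPKM and Rrm2, a ribonucleotide reductase subunit, falling from 76.7 ± 0.50 to 35.5 ± 1.7. Of 45 cytosolic ribosomal protein genes 36 fell and 2, Rps20 and Rps28, rose (adjusted p = 6e-09, adjusted p = 0.222 with an estimated correlation), and Rpl4 dropped from 773 ± 14 to 403 ± 14 RPKM. Ribosomal protein genes have many processed copies in the genome, so single members are uncertain, and with 1 of the 45 sharing no 50-base sequence the list could not be tested on such genes. Nuclear genes of oxidative phosphorylation fell in 24 of 44 cases and rose in 5 (adjusted p = 0.00479, adjusted p = 0.438 with an estimated correlation), among them Cycs, cytochrome c, from 38.4 ± 0.65 to 24.6 ± 0.77 RPKM. Mitochondrially encoded transcripts went the other way, with 12 of 13 rising (adjusted p = 0.025, adjusted p = 0.454 with an estimated correlation), with a loss of the call without a filter on low values (0.105, range 0.00561 to 0.105) at the same median of 0.70. Their share of summed RPKM was 8.46 ± 0.22% in control, 14 ± 1.0% with wild-type vesicles and 12.8 ± 0.21% with deficient vesicles.

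Alveolar type 2 markers rose while those of the transitional state that alveolar cells pass through after injury fell. Of 11 alveolar type 2 genes 9 rose and 1, Etv5, fell (adjusted p = 0.042, adjusted p = 0.274 with an estimated correlation). Sftpb, which encodes surfactant protein B and lies on chromosome 6 at 72304610 to 72314371, rose from 13.6 ± 1.6 to 62.4 ± 7.6 RPKM, Lpcat1, an enzyme of surfactant lipid synthesis, from 19.1 ± 0.54 to 51.8 ± 2.8, and Sftpa1 from 0.0651 ± 0.021 to 1.63 ± 0.19. The type 2 call did not survive leaving out wild-type replicate 1 (adjusted p = 0.0733), wild-type replicate 2 (0.0952), deficient replicate 1 (0.0844) or deficient replicate 2 (0.077), and over all alternatives the adjusted p ranged from 0.0228 to 0.309, the highest without a filter on low values. In these 4 fits the median was 0.46, 0.43, 0.44 and 0.44 against 0.50 with all libraries, and on genes sharing no 50-base sequence it was 1.06 with the call kept (0.0302). Of 12 alveolar type 1 genes 6 rose and 4 fell, without a call for the list at an adjusted p of 0.749. Ager, the receptor for advanced glycation end products and a type 1 marker, rose from 5.05 ± 0.49 to 28.1 ± 3.8 RPKM, and Hopx from 25.0 ± 1.6 to 41.9 ± 2.2, while Gprc5a fell from 78.3 ± 0.39 to 50.8 ± 2.4. Of 15 transitional epithelium genes 10 fell and 2, Cdkn1a and Nupr1, rose (adjusted p = 0.00173, adjusted p = 0.274 with an estimated correlation). Krt19, a simple epithelial keratin, went from 712 ± 18 to 186 ± 23 RPKM, Plaur, the urokinase receptor, from 10.9 ± 0.82 to 2.76 ± 0.12, and Tnip3 from 12.1 ± 0.13 to 3.14 ± 0.25. The 3 wild-type libraries held Ager at 25.9, 25.9 and 32.5 RPKM and Sftpb at 57.7, 58.4 and 71.1, with replicate 3 the highest in both.

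Fibrosis-related lists gave mixed changes. Of 26 extracellular matrix genes 15 fell and 6 rose (adjusted p = 0.0176, adjusted p = 0.425 with an estimated correlation), and the call was lost at a mean RPKM of at least 5 (0.0714, range over the alternatives 0.000607 to 0.0714), where the median was -0.24 against -0.23. Sparc, a matrix-binding glycoprotein, fell from 369 ± 3.1 to 192 ± 1.2 RPKM, and the laminin chain gene Lamb1 rose from 4.32 ± 0.23 to 9.02 ± 0.27. The TGF-beta list had 15 of 27 genes higher and 6 lower, with no call (adjusted p = 0.478). Within it Tgfb1 rose from 10.4 ± 0.45 to 27.0 ± 2.7 RPKM and the inhibitory Smad6 from 8.28 ± 0.047 to 15.3 ± 0.42, while Tgfb3 fell from 17.7 ± 0.22 to 8.04 ± 0.33 and Thbs1, an activator of latent TGF-beta, from 38.2 ± 1.8 to 19.2 ± 1.3. The list for epithelial-mesenchymal transition holds both epithelial and mesenchymal genes, and had 4 of 15 higher and 6 lower (adjusted p = 0.25), with the mesenchymal filament gene Vim falling from 456 ± 8.7 to 266 ± 22 RPKM and N-cadherin, Cdh2, rising from 11.7 ± 0.40 to 20.1 ± 1.3. Wnt pathway genes rose in 19 of 28 cases and fell in 5, Ccnd1 among them, at an adjusted p of 0.0557. Wls, which secretes Wnt proteins, rose from 35.4 ± 0.35 to 73.3 ± 1.3 RPKM, Fzd6 from 23.2 ± 0.97 to 42.2 ± 0.70 and Ctnnb1, which encodes beta-catenin, from 173 ± 4.3 to 280.3 ± 2.3.

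Lipid genes rose and antioxidant genes fell, while the falls of the heat shock and hypoxia lists lay mostly in genes that share sequence, however little, with others. Of 24 cholesterol synthesis genes 20 rose and 0 fell (adjusted p = 0.000104, adjusted p = 0.178 with an estimated correlation), including Lss, which encodes lanosterol synthase, from 9.17 ± 0.30 to 21.7 ± 0.61 RPKM. Of 24 genes of lipid synthesis and uptake 18 rose and 2, Elovl6 and Me1, fell (adjusted p = 0.00479, adjusted p = 0.222 with an estimated correlation). The fatty acid transporter gene Cd36 reached 154 ± 4.1 RPKM from 56.0 ± 1.4, and the lipid droplet gene Plin3 69.5 ± 4.1 from 24.4 ± 0.53. Of 31 NRF2 and antioxidant genes 24 fell and 3, Sod2, Gstm1 and Hmox1, rose (adjusted p = 7.42e-08, adjusted p = 0.146 with an estimated correlation). Thioredoxin reductase, Txnrd1, fell from 104 ± 1.7 to 47.7 ± 0.87 RPKM and glutathione peroxidase, Gpx1, from 125 ± 2.8 to 43.0 ± 2.7. Heat shock genes fell in 13 of 19 cases and rose in 3, Hspa4l, Hspb8 and Cryab (adjusted p = 0.000104, adjusted p = 0.178 with an estimated correlation), with Fkbp4 going from 169 ± 3.8 to 62.7 ± 0.81 RPKM. In the list of the unfolded protein and integrated stress responses 20 of 35 genes fell and 11 rose (adjusted p = 0.0206, adjusted p = 0.266 with an estimated correlation). The chaperone Hspa5 fell from 372 ± 4.0 to 152 ± 5.1 RPKM and Pdia4, a disulfide isomerase, from 118 ± 2.6 to 56.6 ± 1.1, whereas the transcription factor Atf5 rose from 21.7 ± 0.95 to 73.3 ± 6.7. Hypoxia and glycolysis genes fell in 18 of 32 cases and rose in 8 (adjusted p = 0.00578, adjusted p = 0.641 with an estimated correlation), among them the glucose transporter gene Slc2a1 from 18.8 ± 1.6 to 6.75 ± 0.17 and the hexokinase gene Hk2 from 10.7 ± 0.86 to 3.58 ± 0.16. Among genes that share no 50-base sequence with another gene, the calls of the hypoxia (adjusted p = 0.421), heat shock (0.229) and oxidative phosphorylation (0.0576) lists were lost, which were the highest values in ranges that began at 0.000849, 1.72e-05 and 0.00148. The hypoxia median turned from -0.28 to 0.02 over 18 such genes, with 7 higher and 7 lower, against -0.79 over the 14 genes that share sequence. The heat shock median went from -0.61 to -0.07 over 6 genes, with 2 higher and 2 lower, and was -0.69 over the 13 others. Genes with any shared 50-base sequence count among those that share, such as Fkbp4 at 1.8% and Hspd1 at 38.7%. Slc2a1 and Hk2 share 0%. These medians therefore do not show that the falls come from shared reads. The oxidative phosphorylation median was -0.14 over 23 genes against -0.17 over all 44. The unfolded protein list lost its call at a mean RPKM of at least 5 (0.065, range 0.0088 to 0.065), at the same median of -0.25.

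The remaining lists had no camera call with wild-type vesicles. In the p53 and senescence list 21 of 31 genes rose and 7 fell (adjusted p = 0.351), with Trp53inp1 rising from 9.07 ± 0.33 to 31.5 ± 4.3 RPKM. Apoptosis genes rose in 17 of 29 cases and fell in 6 (adjusted p = 0.478), including rises of the pro-death genes Bmf, from 3.20 ± 0.20 to 8.01 ± 0.12, and Casp9, from 3.63 ± 0.099 to 7.50 ± 0.092. Of 22 NF-kB and inflammation genes 11 rose and 7 fell (adjusted p = 0.91), where Ccl2, a monocyte chemokine, fell from 6.93 ± 0.61 to 0.962 ± 0.14 and Tlr2 rose from 2.98 ± 0.23 to 7.33 ± 0.11. Immediate early genes rose in 14 of 26 cases and fell in 6 (adjusted p = 0.25), including rises of Dusp1 and Egr1, and Spry2 rose from 18.1 ± 0.77 to 46.5 ± 2.4 RPKM. The heparan sulfate and syndecan list had 8 of 22 genes higher and 4 lower (0.922), the vesicle and endosome list 14 of 26 higher and 6 lower (0.581), the microRNA machinery 9 of 18 higher and 6 lower (0.85), and the histones 3 of 5 higher and 1 lower (0.85). Rescaling by median-of-ratios factors moved these balances: the higher and lower members were then 8 and 10 for vesicles and endosomes, 5 and 9 for heparan sulfate, 7 and 8 for the microRNA machinery, 7 and 8 for NF-kB, 11 and 8 for apoptosis and 18 and 8 for p53. The TGF-beta list became 12 and 8. Lamp2, a lysosomal membrane protein, rose from 31.2 ± 0.97 to 63.8 ± 1.9 RPKM, and Ago4, an Argonaute gene, from 1.1 ± 0.068 to 4.39 ± 0.16.

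In total 8352 of 11125 tested genes differed between wild-type vesicles and control at a limma adjusted p under 0.05, 5009 higher and 3343 lower, and 844 of them changed by at least 1 on the log2 scale, or 1285 with a pseudocount of 0.1 and 1348 with limma-voom. The values of the 2 groups did not overlap in 78.2% of tested genes, where chance gives 10%. The median over all tested genes was 0.090 on the log2 scale, and after rescaling by median-of-ratios factors the split became 4216 higher and 4211 lower of 8427 genes. Camera called 14 lists, 5 higher and 9 lower, none of which kept the call with an estimated correlation, while fry, which tests whether a list's genes move on balance in 1 direction, called all 27. After the same rescaling all 14 kept their camera call and direction and the Wnt list was added at an adjusted p of 0.0421, while the medians of the S phase list and the heparan sulfate list changed sign. For the NF-kB list and the heparan sulfate list the median was above 0 and camera pointed down. Adjusted over the list alone, the counts differed in 4 of the 27 lists: 11 transitional epithelium genes, 19 hypoxia genes and 37 ribosomal protein genes fell, and 3 lipid genes fell.

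**Figure D3:**
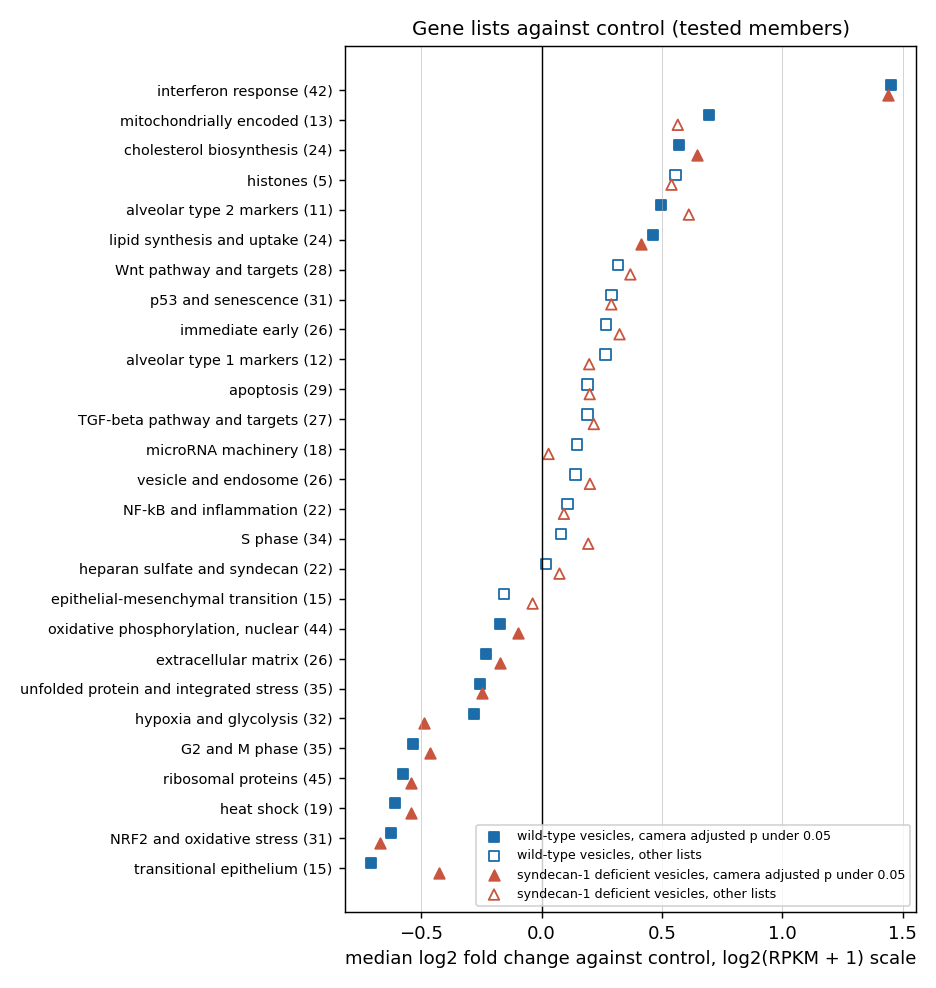
Median log2 fold change against control for each of the 27 tested gene lists, with the number of tested members in brackets, squares for wild-type and triangles for syndecan-1 deficient vesicles. Filled markers have a camera adjusted p under 0.05, and the medians range from -0.71 to 1.45 with wild-type vesicles and from -0.67 to 1.44 with deficient ones.

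The second comparison asks the same of vesicles from syndecan-1 deficient donors. The 12 lists called in both comparisons moved in the same directions. Interferon-response genes rose in 40 of 42 cases, with Cxcl10 falling and Irf1 not called, at a median log2 fold change of 1.44 (camera adjusted p = 1.96e-08, adjusted p = 0.399 with an estimated correlation). Ifit2 reached 38.8 ± 2.4 RPKM and Gbp7 4.06 ± 0.18. Ptgds again led the increases, at 42.0 ± 2.0 RPKM and a log2 fold change of 4.91 ± 0.084 (adjusted p = 2.61e-10), followed by Wif1 at 18.1 ± 4.6 RPKM. The growth factor gene Fgf1 rose from 2.83 ± 0.28 to 21.1 ± 2.0 RPKM, and was among the 12 largest increases in this comparison. Mt2 showed the largest named decrease, to 11.6 ± 2.1 RPKM from 140.1 ± 13, a log2 fold change of -3.49 ± 0.13 (adjusted p = 7.73e-09). Ccnd1 fell to 28.4 ± 1.1 RPKM, Krt19 to 191 ± 13, the endocytic receptor gene Lrp2 from 86.2 ± 2.7 to 18.6 ± 1.6, the growth factor carrier Fgfbp1 from 4.30 ± 0.25 to 0.198 ± 0.016 and the tubulin gene Tubb3 from 26.2 ± 1.0 to 5.39 ± 1.1. Tff2 was listed at 0.0599, 0 and 0.0522 RPKM.

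With deficient vesicles 32 of 35 G2 and M phase genes fell and 0 rose (adjusted p = 9.71e-12, adjusted p = 0.156 with an estimated correlation), as did 39 of 45 ribosomal protein genes (1.38e-11, adjusted p = 0.156 with an estimated correlation). Of 31 NRF2 genes 26 fell and 2 rose (1.13e-10, adjusted p = 0.0643 with an estimated correlation), with the pentose phosphate enzyme gene Pgd at 18.3 ± 0.98 RPKM against 46.9 ± 1.3 in control. Heat shock genes fell in 14 of 19 cases and rose in 3 (4.87e-05, adjusted p = 0.156 with an estimated correlation), hypoxia and glycolysis genes fell in 20 of 32 and rose in 9 (0.000428, adjusted p = 0.5 with an estimated correlation), and unfolded protein and integrated stress genes fell in 21 of 35 and rose in 9 (0.00245, adjusted p = 0.156 with an estimated correlation). Transitional epithelium genes fell in 11 of 15 cases and rose in 2 (5e-04, adjusted p = 0.274 with an estimated correlation), extracellular matrix genes fell in 14 of 26 and rose in 8 (0.0104, adjusted p = 0.382 with an estimated correlation), and nuclear oxidative phosphorylation genes fell in 16 of 44 and rose in 5 (0.00387, adjusted p = 0.399 with an estimated correlation). Cholesterol synthesis genes rose in 20 of 24 cases (0.000137, adjusted p = 0.156 with an estimated correlation), and genes of lipid synthesis and uptake rose in 19 of 24 and fell in 2 (0.0104, adjusted p = 0.274 with an estimated correlation). Sftpb stood at 60.6 ± 3.8 RPKM, Ager at 31.1 ± 1.2 and Hspa5 at 148 ± 3.5.

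Of the lists without a camera call, alveolar type 2 genes rose in 8 of 11 cases and fell in 1 (adjusted p = 0.107), and mitochondrially encoded genes rose in 9 of 13 (0.107). Alveolar type 1 genes rose in 6 of 12 and fell in 3 (0.733), TGF-beta genes rose in 18 of 27 and fell in 6 (0.421), Wnt genes rose in 19 of 28 and fell in 6 (0.194), and genes of epithelial-mesenchymal transition rose in 5 of 15 and fell in 7 (0.148). The p53 list had 18 of 31 higher and 7 lower (0.594), apoptosis 19 of 29 higher and 4 lower (0.209), S phase 22 of 34 higher and 4 lower (0.209), NF-kB 11 of 22 higher and 6 lower (0.788) and immediate early genes 14 of 26 higher and 5 lower (0.556). The counts were 10 higher and 5 lower of 22 for heparan sulfate and syndecans (0.864), 15 and 4 of 26 for vesicle and endosome genes (0.594), 8 and 5 of 18 for the microRNA machinery (0.788), and 3 and 0 of 5 for histones (0.788). After rescaling by median-of-ratios factors the higher and lower members were 9 and 8 for vesicles and endosomes, 6 and 9 for the microRNA machinery, 8 and 9 for heparan sulfate, 7 and 9 for NF-kB and 15 and 10 for S phase. They were 15 and 10 for p53, 11 and 5 for apoptosis, 13 and 7 for TGF-beta and 17 and 9 for Wnt. Adjusted over the list alone, 19 TGF-beta genes and 15 immediate early genes rose and 40 ribosomal protein genes fell, and the other 24 lists had equal counts.

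Of 11125 tested genes 8370 differed between deficient vesicles and control, 5424 higher and 2946 lower, and 813 changed by at least 1 on the log2 scale, or 1284 with a pseudocount of 0.1 and 1340 with limma-voom. The groups did not overlap in 81.0% of tested genes, where chance gives 10%. The median of all tested genes was 0.13 on the log2 scale and became -0.0028 after rescaling by median-of-ratios factors, with 4203 higher and 4194 lower of 8397 genes. All 12 lists called by camera, 3 higher and 9 lower, kept their call and direction after rescaling, and the type 2 list was added at 0.0464. After it the medians of the NF-kB, heparan sulfate and microRNA machinery lists changed sign. Before rescaling, the medians of the NF-kB and microRNA machinery lists were above 0 where camera pointed down. Fry called all 27 lists. On genes sharing no 50-base sequence, the hypoxia and heat shock calls were lost, each at an adjusted p of 0.122 in ranges that began at 3.77e-05 and 2.28e-05. Their medians went from -0.49 to -0.09 and from -0.54 to -0.17, with 9 of 18 and 3 of 6 such genes lower. The extracellular matrix call was lost at a mean RPKM of at least 5 (0.0558, range over the alternatives 0.000367 to 0.0558), at the same median of -0.17.

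Both preparations changed largely the same genes in the same direction. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.944, where simulated groups without effects that share the same controls gave 0.499. The covariance was 0.288 against a simulated 0.0026, a difference of 0.286. The sign was shared by 89.0% of genes, against 66.6% in the simulation. Calls in both comparisons numbered 7221, with 4632 higher in both and 2582 lower in both, where independent lists would give 2442 and 885. With 3 control libraries the controls could not be split into parts of at least 2 libraries. The simulation counts the spread between the shared controls, and its covariance of 0.0026 argues against that spread as the source of the excess. A difference common to all 3 controls would not be seen. The remaining 7 genes were called in opposite directions against control.

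Markers of leukocytes stayed low, while summed fibroblast markers rose through Dcn and summed airway markers fell, with single members in both directions. Summed over 26 macrophage genes, RPKM was 5.94 ± 0.15 in control, 6.07 ± 0.31 with wild-type vesicles and 6.69 ± 0.26 with deficient vesicles, where Cd14 was the most abundant. The 16 neutrophil genes summed to 1.28 ± 0.20, 1.47 ± 0.21 and 1.51 ± 0.44, and the 14 lymphocyte genes to 0.139 ± 0.032, 0.293 ± 0.13 and 0.412 ± 0.055. The 16 fibroblast genes summed to 289.8 ± 4.5, 846.5 ± 77 and 847 ± 68 RPKM. Of these Dcn, a collagen-binding proteoglycan also called decorin, was the most abundant. It rose from 196 ± 4.4 to 787 ± 78 RPKM with wild-type and 787 ± 67 with deficient vesicles, and Pdgfra from 1.12 ± 0.031 to 5.07 ± 0.36 and 5.43 ± 0.17. The rise of Dcn exceeded that of the sum with both preparations, so the fibroblast genes other than Dcn fell in sum. Col1a1 fell from 79.3 ± 0.44 to 46.5 ± 1.5 and 45.7 ± 2.4, and Fbln1 from 13.5 ± 0.29 to 6.89 ± 0.030 and 7.6 ± 0.57. The 17 airway genes summed to 299.9 ± 13, 239.1 ± 3.5 and 238 ± 16 RPKM, Tubb4b being the most abundant. Among them the basal cell factor Trp63 fell from 2.27 ± 0.044 to 0.570 ± 0.022 and 0.553 ± 0.062, and Tppp3 rose from 0.820 ± 0.013 to 2.06 ± 0.14 and 2.52 ± 0.089. The 14 endothelial and erythroid genes summed to 29.3 ± 1.3, 33.2 ± 0.52 and 39.3 ± 6.0 RPKM, Ramp2 being the most abundant. The list of nuclear long noncoding RNAs had 0 genes in the table. These 7 lists had fewer than 5 tested members and were not tested as lists.

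The third comparison asks whether the response differs between vesicles of syndecan-1 deficient and wild-type donors. Whether the 3 libraries of a group had separate donors or vesicle preparations is not known. The p values may therefore measure only the spread between cultures, and cannot by themselves tie a difference to the donor genotype. They also rest on a spread estimated jointly with the controls, whose replicates differed less, so they may be too small for this comparison. Between deficient and wild-type vesicles 2042 of 11125 genes differed, 1438 higher and 604 lower with deficient vesicles, with 20 changed by at least 1 on the log2 scale, and the count of 2042 fell to 0 without wild-type replicate 1, wild-type replicate 2 or deficient replicate 2. The number changed by at least 1 was 37 with a pseudocount of 0.1, 40 with limma-voom, 54 with library weights and 66 without wild-type replicate 3, and 0 where no gene was called. Smad6, the inhibitory SMAD on chromosome 9 at 63953076 to 64022059, was higher with deficient vesicles at 19.1 ± 0.90 RPKM against 15.3 ± 0.42, a log2 difference of 0.30 ± 0.043 (adjusted p = 0.0237), and Id3, a target of bone morphogenetic proteins, at 52.1 ± 3.4 against 39.2 ± 1.8 (0.40 ± 0.057, adjusted p = 0.0237). The cell cycle inhibitor gene Cdkn1b was 45.1 ± 6.1 RPKM against 33.6 ± 1.4. The kinetochore gene Ndc80 was 20.3 ± 0.38 against 15.7 ± 0.74, and with it 13 of 35 G2 and M phase genes were higher and 1 lower, or 6 and 1 after rescaling by median-of-ratios factors, and the list was not called (adjusted p = 0.0505). S phase genes were higher in 10 of 34 cases and lower in 0, or 4 and 1 after the same rescaling, including Hells at 13.2 ± 0.88 against 9.95 ± 1.1 (list adjusted p = 0.0634). Muc5b, a secreted mucin on chromosome 7 at 141839070 to 141873084, was lower at 12.8 ± 0.77 RPKM against 18.8 ± 2.0 (log2 difference -0.52, adjusted p = 0.0237). The metallothionein gene Mt1 was 150.5 ± 19 against 292 ± 55, and Ctgf, a matricellular growth factor, 46.4 ± 1.8 against 62.6 ± 8.5.

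**Figure D4:**
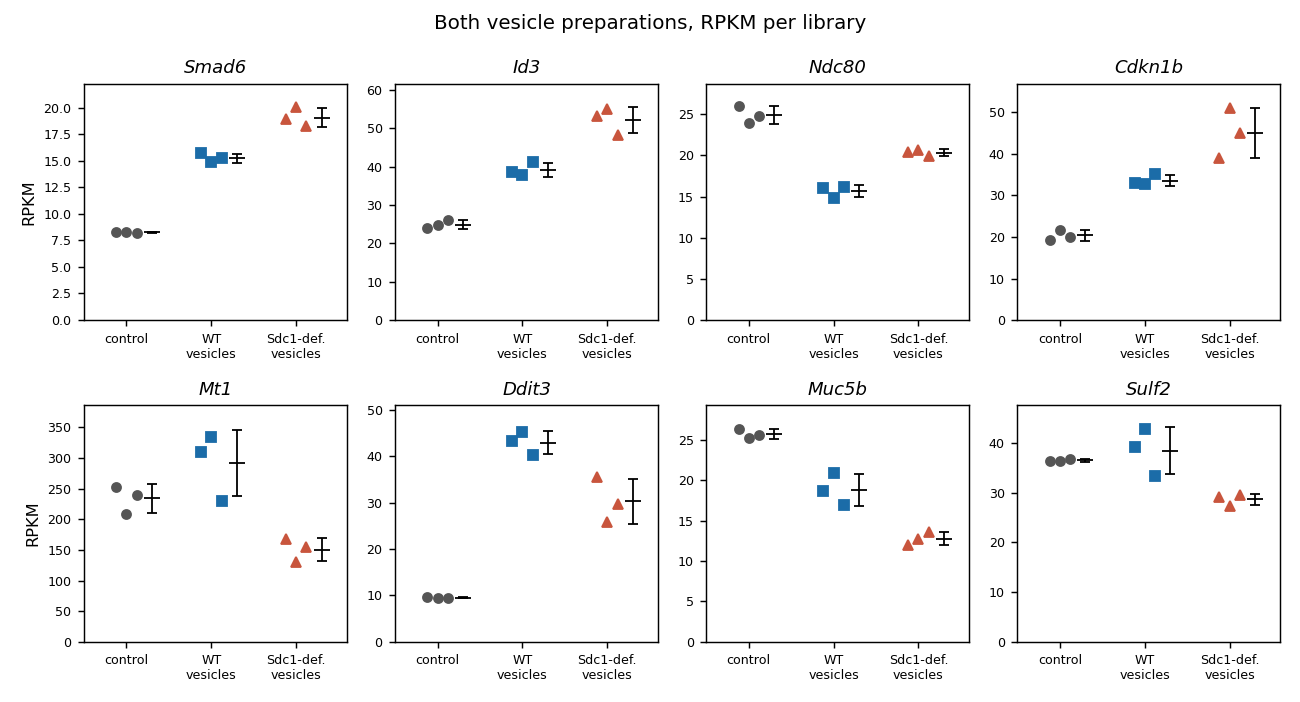
RPKM of 8 genes named for the comparison of the preparations, per library on linear axes from 0, with black bars for the group mean ± SD (n = 3). Smad6, Id3, Ndc80 and Cdkn1b lie higher, and Mt1, Ddit3, Muc5b and Sulf2 lower, with syndecan-1 deficient than with wild-type vesicles.

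Of 35 unfolded protein and integrated stress genes 8 were lower with deficient vesicles and 1 higher (adjusted p = 0.0505), with the stress transcription factor Ddit3 at 30.3 ± 4.8 RPKM against 42.9 ± 2.5 and Atf5 at 54.5 ± 2.6 against 73.3 ± 6.7. NRF2 genes were lower in 6 of 31 cases (0.0505), among them Osgin1 at 10.9 ± 0.55 against 14.9 ± 2.0. Hypoxia and glycolysis was the 1 list called by camera, with 5 of 32 genes lower and 1 higher (adjusted p = 0.00939, adjusted p = 0.718 with an estimated correlation). Its members include Eno1, an enolase gene that shares 26.1% of its 50-base sequences with other genes, at 177 ± 7.5 against 223 ± 18 RPKM, Pfkl, a phosphofructokinase gene, at 12.4 ± 0.65 against 15.2 ± 0.21, and the angiogenic factor gene Vegfa at 19.0 ± 0.69 against 22.4 ± 0.57. Over the alternatives its adjusted p ranged from 0.000575 to 0.0631, and the call was lost at a mean RPKM of at least 5 (0.0631), at the same median of -0.07. Myc was 9.68 ± 0.33 RPKM against 12.8 ± 1.5. In the heparan sulfate list the extracellular sulfatase gene Sulf2 was 28.7 ± 1.1 against 38.5 ± 4.8, and 3 genes were higher and 1 lower of 22 (0.583). Interferon genes were lower in 2 of 42 cases and higher in 0 (0.151), ribosomal protein genes lower in 9 and higher in 5 of 45 (0.575), TGF-beta genes higher in 5 and lower in 1 of 27 (0.575), nuclear oxidative phosphorylation genes higher in 10 and lower in 5 of 44 (0.935), and apoptosis genes higher in 6 of 29 (0.129). Alveolar type 2 genes were lower in 1 of 11 cases (0.873), type 1 genes higher in 2 and lower in 2 of 12 (0.935), and the other lists had between 0 and 5 members called in either direction. After rescaling by the same factors the higher and lower members were 0 and 8 for the unfolded protein list, 3 and 9 for ribosomal proteins, 3 and 1 for TGF-beta, 6 and 6 for oxidative phosphorylation, 3 and 0 for apoptosis and 1 and 1 for heparan sulfate. Adjusted over the list alone, the G2 and M phase count became 16 higher and 1 lower, the hypoxia count 6 lower and 1 higher, and counts differed in 16 of the 27 lists. In 13 lists the median, mean and camera direction differed in sign, and after rescaling the medians of 8 lists changed sign. Fry called 2 lists in 1 direction and 25 when either direction counts.

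The 12 largest increases and 12 largest decreases included several gene copies. Ribosomal pseudogenes Rpl36-ps3, Rpl13-ps3, Rpl9-ps6 and Rpl21-ps4 and the retrogene Rps27rt were higher with deficient vesicles and share between 25.0% and 95.7% of their 50-base sequences with other genes, so their reads are uncertain. Slc24a5, Capn12, Sycp3, Nox1, Chchd2 and Rps27l were also higher. Hbb-bs, a beta globin gene that shares 55%, stood at 7.49, 1.90 and 0.686 RPKM in the 3 deficient libraries and at 0.243, 0.0463 and 0.0449 in the wild-type ones. Among decreases, Ccdc36 stood at 6.65, 10.7 and 1.70 RPKM with wild-type vesicles and 1.57, 0.0811 and 0.0950 with deficient ones, and the respiratory chain gene Ndufa1 at 279.5, 284 and 127 against 116, 79.9 and 96.2. Teddm2, Rps29, Pfdn5, Rpl30, Ndufa3, mt-Nd4l, S100a1 and Ndufaf2 were also among the decreases, with Mt1.

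The number of calls in this comparison depended on single libraries, while the log2 differences moved little when 1 library was left out. The count of 2042 fell to 0 without wild-type replicate 1, wild-type replicate 2 or deficient replicate 2 (2849, 2820 and 3128 genes with an unadjusted p under 0.05), to 2 without deficient replicate 3, and to 732, 900 and 704 without control replicates 1, 2 and 3, and it was 4683 without wild-type replicate 3 and 1895 without deficient replicate 1. In the 3 fits with 0 calls the log2 differences had a correlation of 0.985, 0.977 and 0.979 over genes with those of all libraries, most of which they share. With wild-type replicates 1 and 2 both left out the correlation was 0.7279. The median log2 difference was then 0.0131 against 0.0372, so the differences rest in part on these 2 libraries. Leaving out a control, which does not enter the difference, also lowered the count. The fit shares 1 estimate of the spread over the 3 groups, and control replicates differed less. On recovered reads their chi-square per degree of freedom was 2.52 to 3.50. It was 2.55 to 22.5 between wild-type libraries and 6.04 to 11.2 between deficient ones. The p values of this comparison therefore rest in part on the smaller spread of the controls. With only the 2 vesicle groups in the fit limma called 0 genes, at a smallest adjusted p of 0.0538, while 3397 had an unadjusted p under 0.05, and limma-voom on recovered reads with all 9 libraries called 2414. Without a filter on low values 1 gene was called. The number of lists called by camera went from 1 to 7 without wild-type replicate 1, to 5 without wild-type replicate 2, deficient replicate 1 or deficient replicate 2, and to 2 without wild-type replicate 3 or deficient replicate 3. Rescaling by median-of-ratios factors gave 907 higher and 937 lower of 1844, and kept 1511 of the 2042 calls with their sign (74%). The groups did not overlap in 32.3% of tested genes, where chance gives 10%.

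**Figure D5:**
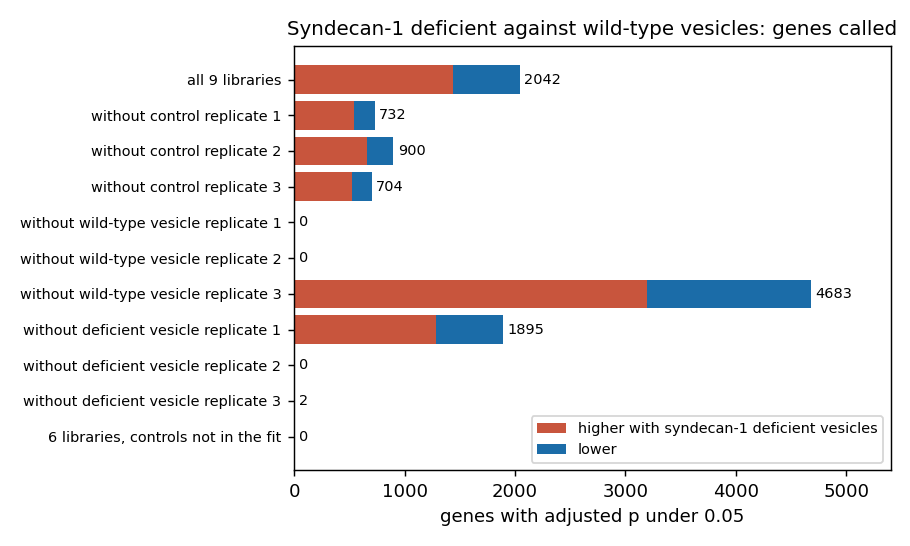
Number of genes with an adjusted p under 0.05 between syndecan-1 deficient and wild-type vesicles (bars, higher and lower stacked), with all 9 libraries, without each library in turn, and with the controls taken out of the fit. The count is 2042 with all libraries and ranges from 0 to 4683.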

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

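Tests chosen only after the result was seen are those of gene length and GC content and of RNA from lavage leukocytes, and the gene lists used for growth signalling and the gastric program were also written after the list results were known.

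The rule for differences between groups picked out 7 genes whose responses to the 2 preparations had opposite signs against control, with a called difference between preparations. Bag5, a cochaperone gene, rose by 0.17 on the log2 scale with wild-type vesicles and fell by 0.16 with deficient ones, a difference of -0.32. The other 6 fell with wild-type and rose with deficient vesicles. They were Mxd3, which encodes a partner of the MYC cofactor MAX, with a difference of 0.69, the ribonuclease H2 subunit gene Rnaseh2b at 0.47, Trim59 at 0.45, Fam92a at 0.36, the histone mRNA exonuclease gene Eri1 at 0.39 and the predicted gene Gm20594 at 2.15. Limma adjusted p of the difference was 0.0237 for Gm20594 and 0.0255 for the others. The opposite genes are 7 of 7221 called in both comparisons, and they share the limits of the comparison between preparations, whose count reaches 0 without single libraries. With wild-type replicates 1 and 2 left out, Mxd3 stood at 0.03 against control (adjusted p = 0.844), so its opposite direction was gone. The other 6 kept their direction with smaller log2 values. That fit has 1 wild-type library and called 0 genes between the preparations, so lost calls there do not count against single genes.

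The libraries with wild-type vesicles formed a pattern of replicates 1 and 2 against replicate 3. Over all tested genes the difference of replicates 1 and 2 from 3 had a spread 2.26 times that between 1 and 2, after scaling to 1 library. Reads shared with gene copies could not be the cause of the whole pattern, since the ratio was 2.131 among genes that share no 50-base sequence. Gene length and GC content explained 2.313% of the variance of the difference, less than the 10% set as the limit for a cause. A difference in handling or in vesicle amount between replicates may remain, and no label describes it.

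For the comparison between preparations, the offset of wild-type replicates 1 and 2 was weighed against a difference of the preparations. If only the offset mattered, the difference of 1 deficient library from wild-type replicate 3 would be unrelated to that of the other deficient libraries from replicates 1 and 2. The mean correlation over genes was 0.4016 (SD 0.126 over 3 choices), so the offset is unlikely as the whole cause, although a graded difference in dose could give the same correlation. Splits of the 6 samples gave 2042 calls for the real grouping and at most 1 for another, and 1 of 10 splits reached the real value, too few splits for a share under 0.05.

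For the response common to both preparations, library composition, RNA of lavage leukocytes carried by the vesicles, and weaker growth signalling were weighed. Rescaling kept at least 85.41% of the calls against control, above the 80% set as the limit. Composition is therefore unlikely to have produced these calls, though it may set their split into higher and lower. Between the preparations the same rescaling kept 74% of the calls, below that limit, so composition remains open there for part of the calls. Summed macrophage, neutrophil and lymphocyte markers rose by 1.259 RPKM at most, from 7.35 ± 0.39 in control to 8.61 ± 0.32 with deficient vesicles, under the 10 RPKM set as the limit, so leukocyte RNA is unlikely as the cause. RNA of other lung cells, such as epithelium or fibroblasts, was not tested as a cause and remains possible. A list of 26 MYC targets fell with both preparations, with a larger median of -0.948, which is consistent with weaker growth signalling in vesicle-treated cells. With an estimated correlation and adjusted over 30 lists, the call held with deficient vesicles (adjusted p = 0.0364) and was lost with wild-type ones (0.0813). Cholesterol synthesis genes went the other way, rising in 20 of 24 cases with each preparation. Immediate early genes rose in 14 of 26 cases and fell in 6 with wild-type vesicles, but camera did not call that list (adjusted p = 0.25). Medium and vesicles also differ in everything else carried by the preparation, so the response could come from vesicles or from other parts of the preparation.

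Splits of the samples gave 8352 calls for wild-type vesicles and 8370 for deficient vesicles against control, where the other 9 splits of each gave at most 0. In each case 1 of 10 splits reached the real value, which is too few splits for a share under 0.05. For all 9 samples 1 of 100 drawn splits reached the real count of 9335, and the highest other count was 8289, in a split that keeps the controls together, which points to a structure of the samples.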

How the results depend on the processing

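Alternatives chosen after the data were seen are limma-voom on recovered reads, leaving out wild-type vesicle replicates 1 and 2, and genes sharing no 50-base sequence. Calls against control kept their size: leaving out 1 library gave 7828 to 8635 genes for wild-type vesicles, 7820 to 8864 for deficient vesicles and 8713 to 9858 for the F test, and genes sharing no 50-base sequence gave 4684, 4733 and 5228, where fewer genes were tested. Between the preparations, leaving out 1 library gave 0 to 4683 genes, no filter 1, library weights 5137, the fit of only the 2 groups compared 0, wild-type replicates 1 and 2 left out 0, and genes sharing no 50-base sequence 1072. Of these, genes sharing no 50-base sequence are fewer genes, and for the others the cause was not tested. With an estimated correlation camera called 0 lists in all 3 comparisons. Leaving out 1 library gave 13 to 15, 12 to 13 and 1 to 7 lists for wild-type vesicles, deficient vesicles and the comparison between them. For the latter, no filter gave 8 lists, a mean RPKM of at least 5 gave 0, library weights 2, wild-type replicates 1 and 2 left out 9, and limma-voom 5, and the cause was not tested. The correlation of the 2 responses was 0.917 with library weights and 0.9117 to 0.9581 when 1 library was left out. Sdc1 with wild-type vesicles stood at -0.1659 with replicates 1 and 2 left out, and the cause was not tested. Leaving out 1 library moved Sdc1 from -0.3635 to -0.2636 with wild-type vesicles, from -0.3378 to -0.2397 with deficient vesicles and from -0.04021 to 0.06846 between them. Of 4948 values of named genes 4371 did not change in call, 547 lost the call (weaker) and 28 gained one (stronger). The 4371 include genes called in neither fit, whatever their sign. Weaker values of genes and lists were unevenly spread, from 0 of 288 with a pseudocount of 0.1 to 70 of 288 without a filter. The 2 reversed values came with wild-type replicates 1 and 2 left out, where Cd14, not called with all libraries, stood at -0.2125 and Mxd3 at 0.02556, and the cause was not tested. Of 525 values of lists 508 kept their call, 16 were weaker and 1 was reversed: the hypoxia list with wild-type vesicles had a median of 0.02434 on genes sharing no 50-base sequence, with 18 of its 32 genes left, and the cause was not tested. With the replicate number as a block the counts were 8331, 8354, 1681 and 9262. The same number correlated best in 7 of 18 pairs of a library and another group, with correlations of deviations between -0.196 and 0.285. The data thus gave no sign that numbers pair the samples, but 3 libraries per group are too few to exclude it. Depths of 24353257 to 33558660 reads limit the precision of genes near the filter.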

Other observations

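The lists of MYC targets, FOXO targets and gastric genes were written after the list results were known, and each test was set down before it was run.

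Weaker growth signalling was tested as a hypothesis for the vesicle response, because cyclin and ribosomal protein genes fell. Of 26 MYC targets 25 fell and 1 rose with wild-type vesicles, and the same numbers were found with deficient vesicles, with medians of -0.948 and -0.972. Adjusted over the 3 lists written for these tests, camera gave p of 6.8e-13 and 2.29e-14 with limma, and adjusted p = 0.00973 and 0.00728 with an estimated correlation. Of 19 tested FOXO targets, which growth factor signalling represses, 17 rose and 1 fell with wild-type vesicles and 16 rose and 1 fell with deficient ones, at medians of 0.53 and 0.64. Their camera p adjusted over the same 3 lists were 0.000934 and 0.00199, and adjusted p = 0.0332 and 0.0424 with an estimated correlation. Adjusted over 30 lists, these 3 and the 27 fixed ones, the MYC list gave 3.8e-12 and 2.29e-13 and the FOXO list 0.00207 and 0.00358. With an estimated correlation the values over 30 lists were adjusted p = 0.0813 and 0.0364 for MYC and 0.132 and 0.13 for FOXO, so only the MYC list with deficient vesicles kept its call. Of the listed genes, 1 MYC target and 3 FOXO targets also belong to a fixed list. The directions of both lists are those expected of weaker growth signalling. Cholesterol synthesis genes did not follow: with wild-type vesicles they rose in 20 of 24 cases and fell in 0 (camera adjusted p = 0.000104, 0.178 with an estimated correlation). The counts were the same with deficient vesicles (0.000137, 0.156 with an estimated correlation). With wild-type vesicles immediate early genes rose in 14 of 26 cases and fell in 6, and S phase genes rose in 16 of 34 and fell in 4. With deficient vesicles 14 immediate early genes rose and 5 fell, and 22 S phase genes rose and 4 fell. Camera called neither of these 2 lists with wild-type (adjusted p = 0.25 and 0.515) or deficient vesicles (0.556 and 0.209). With wild-type vesicles 5009 of all 11125 tested genes were called higher. After rescaling by median-of-ratios factors 12 S phase genes rose and 11 fell with wild-type vesicles, and 15 and 10 with deficient ones. The MYC and FOXO calls depend on the correlation and on the number of lists adjusted over. A change of medium or serum content along with the vesicles could give the same values.

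The trefoil factor genes Tff1 and Tff2, secreted peptides of gastric mucus cells, were nearly lost in vesicle-treated cells, and a loss of a gastric-type program was tested. The list written for the test does not hold these 2 genes. Only 3 of 23 listed gastric genes were tested, and 1 of them was called lower and 1 higher in each comparison with control. Equal numbers lower and higher met the limit set against the explanation, but 3 members are fewer than the 5 asked of a list, so this explanation and its absence cannot be told apart.

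Replicates differed in how far they exceeded counting noise. The chi-square per degree of freedom on recovered reads was 2.52 to 3.50 between controls and 2.55 between wild-type replicates 1 and 2, but 16.4 and 22.5 between these and replicate 3, and 6.04 to 11.2 among the deficient libraries.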
